A study of Mus musculus with 15 samples.

How the data were processed

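Bulk RNA sequencing was carried out on cortical tissue of wild-type C57BL/6J mice taken 3 hours after a session of repetitive transcranial magnetic stimulation. Per the labels, 5 animals received intermittent theta-burst stimulation (iTBS), 5 received continuous theta-burst stimulation (cTBS) and 5 received sham stimulation. The sample titles name somatosensory cortex and the series design names sensorimotor cortex, so the dissected area is called cortex here. Per the labels' protocols, RNA was extracted with an RNeasy Mini kit and libraries were made with a stranded total RNA kit after ribosomal RNA depletion. Total RNA libraries of this kind hold unspliced and nuclear RNA beside mature messenger RNA.

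The authors deposited a table of raw counts per Ensembl gene for the 15 libraries, with no normalization. They also deposited a table of variance-stabilized values on a log2-like scale for the genes with any count. Per the submitters' processing notes, fastp, STAR and DESeq2 were used with the mouse build GRCm39 (mm39); their roles, versions and settings are not given in the sources used here. The read counter, the annotation release and the strand setting of the counting are not given in the sources used here either. Overlapping and antisense genes, and mitochondrial genes that share reads with nuclear pseudogenes, are therefore uncertain. Gene names and gene classes were taken by Ensembl identifier from an annotation of an earlier mouse assembly, so no coordinates are given. Of 56748 identifiers, 52073 had a name, and these held 97.7% of all counts. Every gene named carries the symbol matched in this way.

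The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the raw counts. All 15 libraries entered a model with a term per group, with trimmed-mean (TMM) scaling and the default expression filter by group. The filter kept 22998 of the 45315 genes with counts and 99.9% of the counts. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels in CPM, counts scaled to equal library size, were computed from the deposited counts. For named genes, the library size was the total over tested genes multiplied by the TMM factor. For Malat1, Ttr, Xist and Ddx3y it was the library total alone, so CPM values of these genes are on a slightly different scale. Group levels in CPM are given as mean ± SD over 5 libraries per group.

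Gene lists for cell types, brain regions, activity-response programmes and metabolic functions were fixed before the data were examined, as were the sample groups, the tests, the rule for named genes and the alternatives, except where stated. Of 766 list symbols, 748 were matched, and 43 of 45 lists had at least 3 tested members. Lists were tested with camera (limma 3.58.1) using a preset correlation between genes of 0.01, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. The mean log2 CPM of a list in each library, its level, was compared between groups by a two-sided exact permutation test. With 5 against 5 there are 252 assignments, so the smallest p is 0.00794. The 129 level tests were adjusted together, as were 21 tests of library measures.

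Genes were named by a fixed rule. It takes up to 8 higher and 8 lower genes with adjusted p under 0.05 and mean CPM of at least 1. Where fewer than 10 qualified, genes with the next smallest p filled the number up to 10. The rule adds the 3 members with the smallest p in each called list, given here for the lists described, and a set of plasticity genes: Fos, Arc, Npas4, Egr1, Nr4a1, Bdnf, Homer1, Nptx2, Gria1, Grin1 and Gad1. Some genes that the rule takes are not reported here. The lists described are the 8 called with the smallest p in each comparison and the immediate early, late activity-response, glucocorticoid-response and circadian clock lists; this selection was made after the list results were seen. Counts of members that passed adjusted over their list alone come from lists picked in this way. They are therefore no separate support for a list. Malat1, Ttr, Xist and Ddx3y describe libraries; Malat1 and Ttr were chosen after their values were seen.

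The fold changes of both stimulation protocols against sham share the sham libraries. Their correlation and the genes they share were set beside 20 negative binomial simulations of unchanged groups, with each gene drawn independently. Both were computed again with the sham libraries split between the comparisons (for shared genes, added after the data were seen). Relations between library measures were computed over deviations from group means, with permutation p-values from 100000 resamples. The main test was tried on simulated data for 22998 genes, built from the means, dispersions and library sizes of all 15 libraries. Known fold changes were put into the iTBS libraries, in genes with mean CPM of at least 1. Of 50 genes per fold size, the test of iTBS against sham recovered 14% at 1.25-fold, 66% at 1.5-fold, 80% at 2-fold and 90% at 3-fold, with 5 false calls among 130. Each gene was drawn independently, so recovery and false calls where genes move together were not measured. No deposited library repeated another: over the 105 pairs of libraries, the chi-square per gene ran from 5.21 to 76.8.

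Alternatives were median-of-ratios scaling, no expression filter, a filter of at least 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma-trend on the deposited variance-stabilized values, the libraries of a pair of groups alone, a replicate block, covariates (library number, Y-linked gene level, oligodendrocyte marker level, a surrogate variable from sva 3.50.0) and leaving out each library in turn. Added after the data were seen were covariates for the level of nuclear-retained noncoding RNAs, alone and with the striatal marker level, the library number as a covariate in the list tests, and a fit without the 3 libraries highest in choroid plexus markers.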

Results

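The data were gene counts from cortex of mice that had received iTBS, cTBS or sham stimulation 3 hours earlier, with 5 animals per group. Repetitive transcranial magnetic stimulation drives cortical tissue through the skull with magnetic pulses, and both protocols deliver them in theta-rhythm bursts, either interrupted (iTBS) or unbroken (cTBS). Total counts per library ran from 15385070 to 47807723, and 32299 to 35449 genes were detected. The Y-linked gene Ddx3y was at 46.9 to 67.9 CPM in the 15 libraries and Xist, transcribed from an inactive X chromosome, was at no more than 0.416 CPM. Y-linked genes were not called as a group (adjusted p = 0.999 for iTBS against sham, 0.513 for cTBS against sham and 0.541 for iTBS against cTBS). The biological coefficient of variation was 20.1%.

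Libraries differed widely in RNAs that stay in the nucleus. Malat1, an abundant nuclear noncoding RNA, ran from 985 CPM in cTBS 4 to 10000 CPM in sham 3, and the first principal component held 62.4% of the variance. The mean level of the nuclear-retained noncoding RNAs was 6.77 ± 0.52 (log2 CPM, SD, n = 5) in cTBS, 7.58 ± 0.66 in sham and 7.65 ± 0.49 in iTBS. The exact permutation p was 0.0714 for cTBS against sham and 0.0476 for iTBS against cTBS, both 0.238 after adjustment over 21 tests. Total counts were 40198200 ± 3814620 in cTBS, 29887800 ± 10966400 in sham and 29745100 ± 8461780 in iTBS (exact permutation p = 0.0794 for cTBS against sham and 0.0238 for iTBS against cTBS, both 0.238 adjusted). Over deviations from group means in 15 libraries, the nuclear RNA level followed log2 total counts with Pearson r = -0.655 (permutation p = 0.00665, adjusted p = 0.0116 over 7 relations) and Spearman rho = -0.514 (permutation p = 0.0527). Without the 2 libraries farthest from the median total, r was -0.743. Ttr, a transcript of choroid plexus, ran from 0.780 to 249 CPM, with 240 CPM in sham 2, 249 CPM in sham 5 and 221 CPM in cTBS 4.

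**Figure D1:**
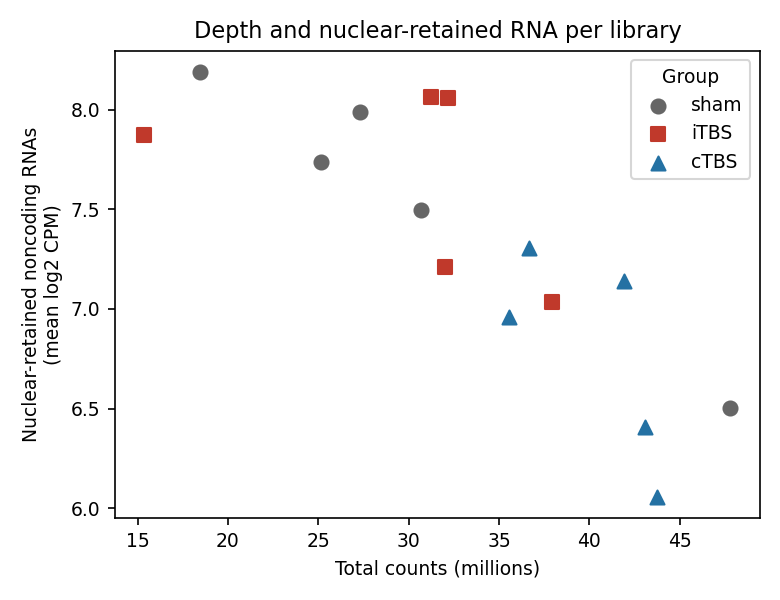
Each point is a library, with total counts on the x axis and the mean log2 CPM of nuclear-retained noncoding RNAs on the y axis, by group. The deepest library, sham 4 at 47807723 counts, lies at a level of 6.50, and the cTBS libraries average 6.77.

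The comparison of iTBS with sham asked which genes differed 3 hours after the intermittent protocol. Genes induced by glucocorticoids, the adrenal stress hormones, were lower as a group after iTBS: 17 of 18 members lay below sham, with a median log2 fold change of -0.21 (camera, adjusted p = 2.14e-12). The call was lost when the correlation between genes was estimated (adjusted p = 0.132 with an estimated correlation). Among its members, Fkbp5, a co-chaperone of the glucocorticoid receptor, was at 22.6 ± 1.36 CPM against 28.4 ± 3.08 in sham (log2 fold change -0.33 ± 0.11, SE). Tsc22d3, which encodes the anti-inflammatory protein GILZ, was at -0.27 ± 0.10, and the kinase gene Sgk1 at -0.56 ± 0.23. At unadjusted p under 0.05 there were 6 lower members, and 0 passed adjusted over the list alone or over all genes. The level of this list was 4.57 ± 0.19 (log2 CPM, SD, n = 5) in iTBS and 4.80 ± 0.09 in sham (exact permutation p = 0.0476, adjusted p = 0.271).

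The glucocorticoid level also moved with the library number in the sample descriptions, over which the 3 groups were interleaved. Over deviations from group means in 15 libraries, Pearson r was 0.810 (permutation p = 0.00033, adjusted p = 0.00182 over 7 relations), Spearman rho was 0.743 (permutation p = 0.00224), and r was 0.807 without the 2 farthest libraries. With the library number as a covariate, the list's median for iTBS against sham was -0.17 (camera, adjusted p = 1.53e-07).

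**Figure D2:**
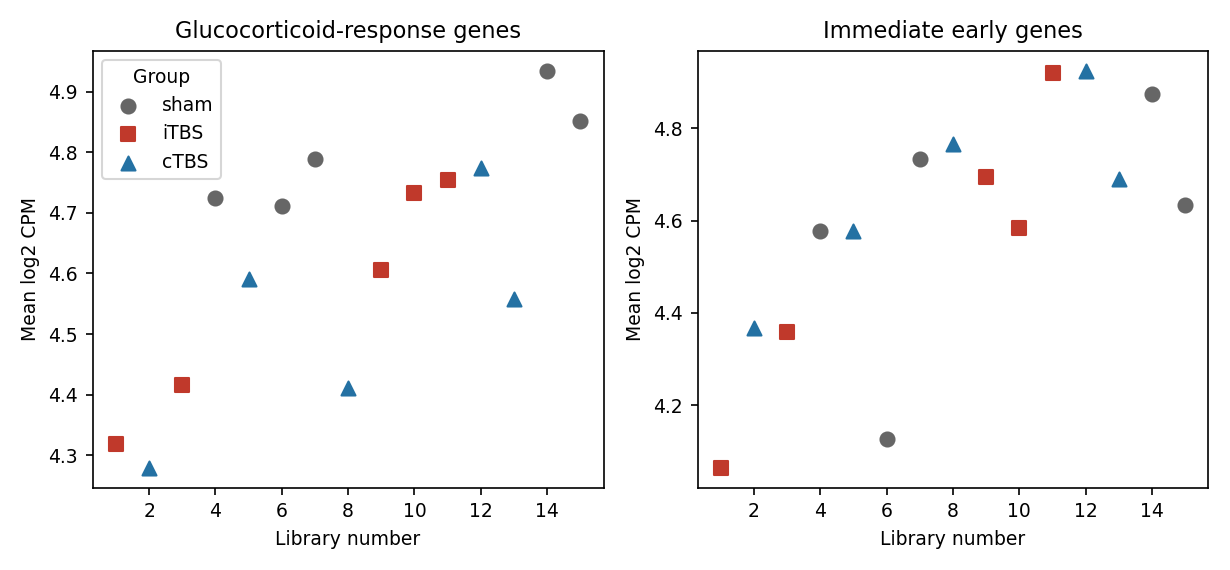
Each point is a library, placed by its library number on the x axis and by the mean log2 CPM of a gene list on the y axis, by group. The glucocorticoid-response level averages 4.57 in iTBS, 4.52 in cTBS and 4.80 in sham, and rises with the library number within groups (r = 0.810 over deviations from group means).

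Other groups were called lower after iTBS with camera's preset correlation. Cytosolic ribosomal protein genes had a median of -0.08, with 53 of 55 members lower (adjusted p = 1.78e-08; adjusted p = 0.745 with an estimated correlation), and Rpl38 was at -0.18 ± 0.11. The call was lost without iTBS 2 (adjusted p = 0.148) or sham 4 (adjusted p = 0.203), and that of the cholesterol synthesis genes without sham 4 (adjusted p = 0.0782). Cholesterol synthesis genes had a median of -0.08, with 19 of 21 lower (adjusted p = 9.90e-07; adjusted p = 0.526 with an estimated correlation). In this list 2 members passed adjusted over the list alone and 0 over all genes, and Mvd and Pmvk, enzymes of the mevalonate pathway, were at -0.23 ± 0.07 and -0.25 ± 0.08. Late activity-response genes, a slower wave of transcription after neuronal firing, had a median of -0.09 (adjusted p = 0.00437; adjusted p = 0.798 with an estimated correlation). Among them Tiparp was at -0.53 ± 0.14, Dusp4 at -0.48 ± 0.21 and Plk2 at -0.20 ± 0.09, with 1 member passing adjusted over the list alone. Circadian clock genes had a median of -0.04 (adjusted p = 0.00685; adjusted p = 0.531 with an estimated correlation), with Per1 at -0.46 ± 0.19 and Ciart at -0.59 ± 0.25. Both calls were lost without iTBS 2 (adjusted p = 0.197 for late activity-response and 0.116 for clock genes), iTBS 4 (0.0708 and 0.0502) or sham 4 (0.782 and 0.632), and the first also without sham 5 (0.361).

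Markers of neighbouring tissue and of blood vessels also differed. Choroid plexus markers had a median of -1.05, with 12 of 12 lower (adjusted p = 7.02e-07; adjusted p = 0.531 with an estimated correlation). Thalamic neuron markers had a median of -0.48, with 9 of 9 lower (adjusted p = 7.02e-07; adjusted p = 0.526 with an estimated correlation), and Prkcd was at 5.25 ± 1.04 CPM against 17.4 ± 26.6 in sham. Without sham 2 the thalamic median was -0.04 and the call was lost (adjusted p = 0.528). Without sham 2, sham 5 and cTBS 4 the choroid plexus median was 0.35 (adjusted p = 0.0366). Meningeal and fibroblast markers were higher, with a median of 0.11 and 13 of 14 members higher (adjusted p = 4.80e-05; adjusted p = 0.526 with an estimated correlation); the collagen genes Col3a1, Col1a2 and Col1a1 were at 0.51 ± 0.14, 0.61 ± 0.23 and 0.94 ± 0.39. Without iTBS 3, where Col1a2 was at 63.3 CPM and Col1a1 at 90.4 CPM, the last 2 were at 0.28 and 0.49. Endothelial and mural cell markers had a median of 0.08 (adjusted p = 2.67e-04; adjusted p = 0.526 with an estimated correlation), with Pdgfrb, a pericyte receptor, at 0.23 ± 0.08. Striatal projection neuron markers had a median of 0.25, with 18 of 18 higher (adjusted p = 0.00145; adjusted p = 0.798 with an estimated correlation), and -0.11 without iTBS 2 (adjusted p = 0.889). Their call was also lost without sham 3 (adjusted p = 0.597), sham 4 (adjusted p = 0.195) and sham 5 (adjusted p = 0.0899).

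Immediate early genes, the first transcripts induced by neuronal activity, were not called as a group after iTBS (median -0.13, adjusted p = 0.319); they were called lower without sham 2 (adjusted p = 1.20e-04) or iTBS 5 (adjusted p = 3.48e-04). Npas4, a transcription factor induced by calcium entry, was at 34.0 ± 7.63 CPM against 26.2 ± 3.94 in sham (0.38 ± 0.16). Fos was at -0.03 ± 0.20, Arc at -0.37 ± 0.25, Egr1 at -0.06 ± 0.20 and Nr4a1 at -0.12 ± 0.24. Bdnf, the neurotrophin, was at -0.04 ± 0.13, and the glutamate receptor genes Gria1 and Grin1 were at -0.00 ± 0.08 and 0.09 ± 0.10. The genes with the smallest p, none of which passed, included Smad6, an inhibitor of BMP signalling, at 1.01 ± 0.21, and Klf15, a glucocorticoid-induced transcription factor, at -0.38 ± 0.08. Rhou and Klf10 were at -0.26 ± 0.06 and -0.56 ± 0.15, and Hunk, Atad2 and Ddit4l at 0.27 ± 0.07, 0.24 ± 0.06 and 0.37 ± 0.10.

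By edgeR, 0 of 22998 genes passed for iTBS against sham (smallest adjusted p = 1.00), and 443 had an unadjusted p under 0.05 (219 higher, 224 lower), against 1149.9 by chance. That number was 816 with the nuclear RNA level as a covariate, 1346 with the striatal level added to it and 920 with a surrogate variable. In the fit with both levels 0 genes passed (edgeR, smallest adjusted p = 0.0965). DESeq2, limma-voom with quality weights and limma-trend each called 0 genes. Groups without overlap were found in 0.452% of genes, against 0.794% by chance. Of 43 lists, 14 were called (4 higher, 10 lower), 8 without iTBS 2 and 9 without iTBS 4, and 0 with an estimated correlation. With the nuclear RNA level as a covariate, chosen after the data were seen, 10 were called (4 higher, 6 lower), and the calls of the circadian clock and late activity-response lists were lost (adjusted p = 0.0676 and 0.0729).

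The comparison of cTBS with sham asked the same of the continuous protocol. Nuclear-retained noncoding RNAs were lower after cTBS and genes of protein synthesis, respiration, myelin and GABA signalling were higher as groups with the preset correlation, and each of these calls was lost when the correlation between genes was estimated (adjusted p = 0.476 with an estimated correlation). The call of the respiration list was also lost with the nuclear RNA level as a covariate (adjusted p = 0.105), and those of the myelin and GABA lists with the nuclear RNA and striatal levels as covariates, chosen after the data were seen, where their medians were -0.0045 (adjusted p = 0.886) and -0.0184 (adjusted p = 0.696). The nuclear-retained list had a median of -0.99, with 10 of 11 members lower (camera, adjusted p = 1.33e-04; adjusted p = 0.476 with an estimated correlation). In it 10 members passed adjusted over the list alone and 0 over all genes; Kcnq1ot1, an imprinted antisense RNA, was at 62.7 ± 33.8 CPM against 167 ± 75.7 in sham (-1.41 ± 0.42), and Mirg and Rmst were at -1.08 ± 0.39 and -0.57 ± 0.21. Cytosolic ribosomal protein genes had a median of 0.22, with 54 of 55 higher (adjusted p = 5.30e-17; adjusted p = 0.476 with an estimated correlation). At unadjusted p under 0.05 there were 35 higher ribosomal genes, 0 passed adjusted over the list alone, and Rps4x was at 96.1 ± 5.32 CPM against 79.6 ± 8.07 (0.27 ± 0.07).

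Nuclear-encoded oxidative phosphorylation genes had a median of 0.19, with 28 of 33 higher (adjusted p = 3.91e-07; adjusted p = 0.476 with an estimated correlation), and Sdhb and Ndufs3 were at 0.28 ± 0.08 and 0.19 ± 0.06. Oligodendrocyte and myelin markers had a median of 0.19, with 17 of 18 higher (adjusted p = 1.07e-04; adjusted p = 0.476 with an estimated correlation), and Cldn11 and Cnp were at 0.25 ± 0.10 and 0.26 ± 0.11. Genes of GABA receptors and GABA synthesis had a median of 0.11, with 17 of 18 higher (adjusted p = 1.07e-04; adjusted p = 0.476 with an estimated correlation). In this list 2 members passed adjusted over the list alone and 0 over all genes. Slc32a1, the vesicular GABA transporter, was at 0.41 ± 0.12, the extrasynaptic receptor subunit Gabrd at 0.21 ± 0.06, and Gad1, which makes GABA, at 383 ± 45 CPM against 321 ± 30.6 (0.25 ± 0.09). Microglia markers had a median of 0.18, with 14 of 14 higher (adjusted p = 1.30e-04; adjusted p = 0.476 with an estimated correlation), and the complement gene C1qc was at 0.24 ± 0.08. Actin and spine cytoskeleton genes had a median of 0.12, with 22 of 24 higher (adjusted p = 1.30e-04; adjusted p = 0.476 with an estimated correlation). Striatal projection neuron markers had a median of 0.70, with 18 of 18 higher (adjusted p = 7.30e-08; adjusted p = 0.476 with an estimated correlation). The opioid peptide gene Pdyn was at 0.56 ± 0.21, and Ppp1r1b, the dopamine-signalling protein DARPP-32, at 175 ± 52.4 CPM against 109 ± 37.6 (0.68 ± 0.28). With the nuclear RNA level alone as a covariate, the oxidative phosphorylation list had a median of 0.05, and the calls of the GABA (median 0.01, adjusted p = 0.383), microglia (median 0.06, adjusted p = 0.178) and actin lists (median -0.01, adjusted p = 0.331) were lost, and that of the nuclear-retained list, whose mean is the covariate (median 0.02, adjusted p = 0.659). The ribosomal and myelin lists were called higher in that fit, with medians of 0.09 and 0.13.

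Glucocorticoid-response genes were lower after cTBS too, with a median of -0.18 and 15 of 18 members lower (adjusted p = 0.0142; adjusted p = 0.476 with an estimated correlation). Here 3 members passed adjusted over the list alone and 0 over all genes: Hif3a at -1.01 ± 0.24, the lipid droplet gene Plin4 at -1.15 ± 0.31 and Arrdc2 at -0.47 ± 0.14. The level of the list was 4.52 ± 0.19 (log2 CPM, SD, n = 5) against 4.80 ± 0.09 (exact permutation p = 0.0238, adjusted p = 0.271). The call was lost without cTBS 1 (adjusted p = 0.0657), cTBS 3 (adjusted p = 0.0505), cTBS 5 (adjusted p = 0.0627) or sham 4 (adjusted p = 0.337). With the library number as a covariate the median was -0.15 (adjusted p = 0.0213).

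Immediate early genes were not called after cTBS (median 0.02, adjusted p = 0.124), and were with the library number as a covariate (median 0.08, adjusted p = 0.0259), without cTBS 1 (median 0.15, adjusted p = 0.0166) or without sham 3 (median 0.07, adjusted p = 0.0457), and with the nuclear RNA and striatal levels as covariates (median 0.16, adjusted p = 0.00123). Fos was at 50.4 ± 9.55 CPM against 37.4 ± 5.73 in sham (0.43 ± 0.19, edgeR adjusted p = 0.193) and Npas4 at 0.36 ± 0.16. Arc was at -0.11 ± 0.25, Egr1 at -0.14 ± 0.20, Bdnf at -0.06 ± 0.13 and Homer1, a postsynaptic scaffold, at -0.24 ± 0.11. Late activity-response genes were not called (adjusted p = 0.452), and the direction of their test was higher while their median was -0.01. They were called lower with the nuclear RNA level as a covariate (median -0.11, adjusted p = 0.00114). Choroid plexus and thalamic markers were not called (median -0.65, adjusted p = 0.408, and median -0.21, adjusted p = 0.452). The genes with the smallest p, none of which passed (edgeR adjusted p = 0.144), included the protocadherin gene Pcdh20 at 33.4 ± 1.98 CPM against 25.2 ± 0.866 (0.40 ± 0.07) and the kinase gene Hunk at 0.38 ± 0.07. Htr1a, a serotonin receptor, was at 0.51 ± 0.11, Clpp, a mitochondrial protease, at 0.32 ± 0.06, Osbpl3 at -0.45 ± 0.09, Abcc4 at -0.44 ± 0.09 and Igsf9b, an adhesion protein of inhibitory synapses, at -0.57 ± 0.12.

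By edgeR, 0 of 22998 genes passed for cTBS against sham (smallest adjusted p = 0.144), and 5623 had an unadjusted p under 0.05 (1565 higher, 4058 lower), against 1149.9 by chance. That number was 1338 with the nuclear RNA level as a covariate, 1453 with a surrogate variable, 3438 with the oligodendrocyte marker level, 3680 with the Y-linked gene level and 2673 without sham 2, sham 5 and cTBS 4. DESeq2 called 471 genes (58 higher, 413 lower), limma-voom with quality weights 5461 (1569 higher, 3892 lower) and limma-trend on the deposited values 0; without sham 4, edgeR called 5726 (2145 higher, 3581 lower), and without iTBS 1 it called 1 gene, Pcdh20 (0.45 ± 0.06, adjusted p = 0.0270). Sham 4 had the lowest nuclear RNA level of the sham libraries (6.50). Groups without overlap were found in 1.34% of genes, against 0.794% by chance. Of 43 lists, 18 were called (16 higher, 2 lower) with the preset correlation and 0 with an estimated correlation. The split turned with the nuclear RNA level as a covariate, where 14 were called (5 higher, 9 lower), and 13 with the striatal level added (4 higher, 9 lower).

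**Figure D3:**
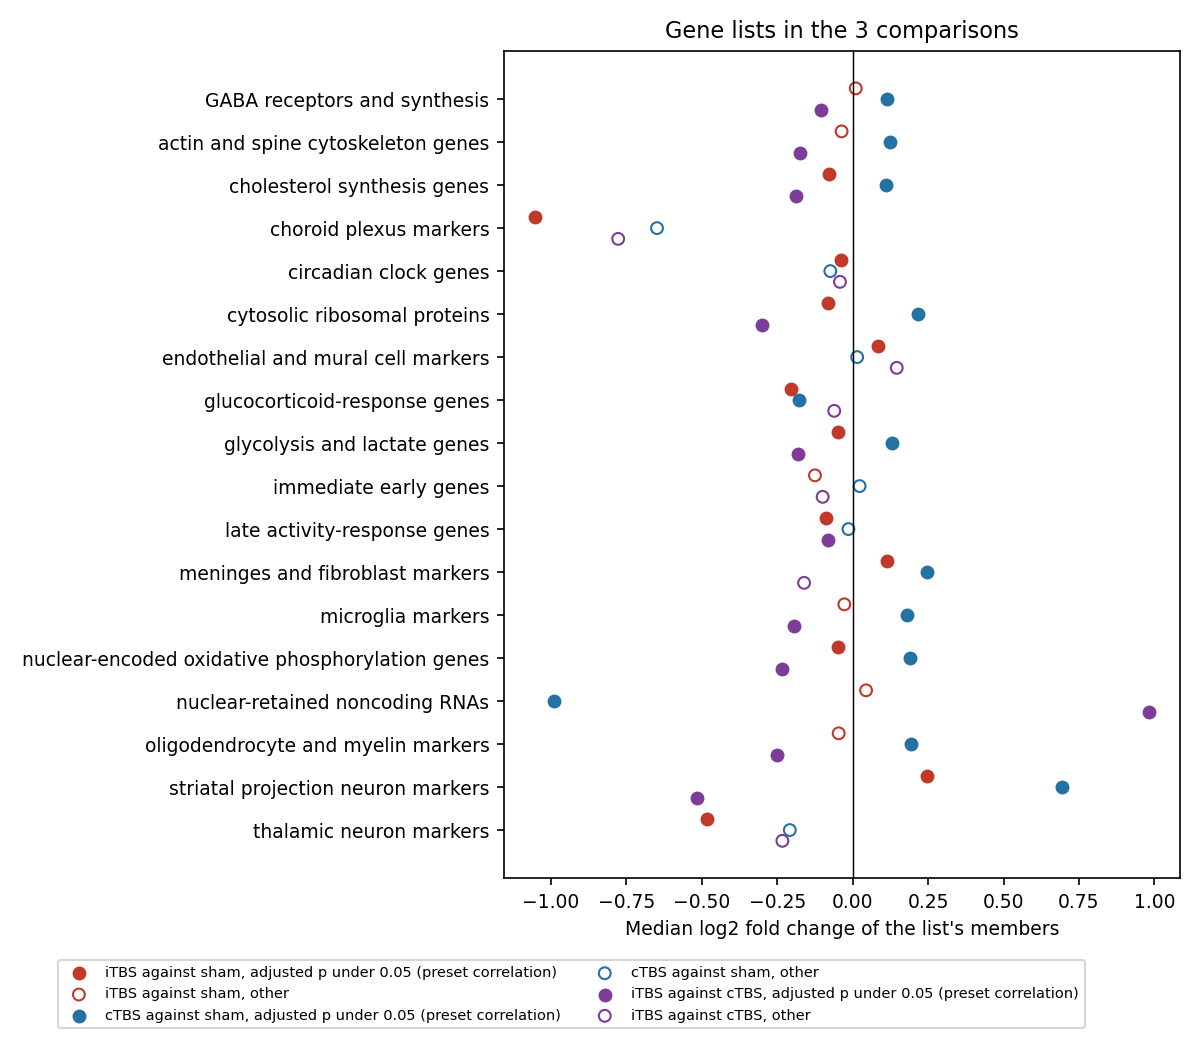
Median log2 fold change of the members of each list on the x axis, for the 3 comparisons; filled points had adjusted p under 0.05 by camera with the preset correlation. Ribosomal protein genes lie at -0.08, 0.22 and -0.30 and glucocorticoid-response genes at -0.21, -0.18 and -0.06 for iTBS against sham, cTBS against sham and iTBS against cTBS; with an estimated correlation 0 lists were called in any comparison.

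The direct comparison of iTBS with cTBS asked where the protocols differed. Ribosomal protein genes were lower after iTBS than after cTBS, with a median of -0.30 and 53 of 55 members lower (camera, adjusted p = 8.49e-25; adjusted p = 0.372 with an estimated correlation). In this list 48 members passed adjusted over the list alone and 0 over all genes; Rps4x was at 74.7 ± 6.75 CPM against 96.1 ± 5.32 (-0.36 ± 0.07), Rpl6 at -0.29 ± 0.07 and Rpl10 at -0.38 ± 0.09. Oxidative phosphorylation genes had a median of -0.23, with 28 of 33 lower (adjusted p = 1.37e-08; adjusted p = 0.372 with an estimated correlation), and 16 passed adjusted over the list alone. Cholesterol synthesis genes had a median of -0.19, with 19 of 21 lower (adjusted p = 5.98e-08; adjusted p = 0.372 with an estimated correlation). In it 12 members passed adjusted over the list alone and 0 over all genes, with Mvd at -0.31 ± 0.07 and Sqle at -0.25 ± 0.06. This was the 1 list called by fry, which tests whether genes of a list move in a direction (adjusted p = 0.0450).

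Glycolysis and lactate genes had a median of -0.18 (adjusted p = 2.45e-05; adjusted p = 0.448 with an estimated correlation), with 5 passing adjusted over the list alone and the lactate transporter gene Slc16a1 at -0.30 ± 0.07. Oligodendrocyte and myelin markers had a median of -0.25, with 18 of 18 lower (adjusted p = 1.13e-05; adjusted p = 0.448 with an estimated correlation), and Mog was at -0.31 ± 0.11. Actin and spine cytoskeleton genes had a median of -0.17 (adjusted p = 2.32e-05; adjusted p = 0.448 with an estimated correlation), with Marcksl1 at -0.42 ± 0.12, and microglia markers -0.20 (adjusted p = 3.85e-04; adjusted p = 0.448 with an estimated correlation). Nuclear-retained noncoding RNAs were higher, with a median of 0.98 and 11 of 11 members higher (adjusted p = 3.52e-04; adjusted p = 0.448 with an estimated correlation). There 9 members passed adjusted over the list alone and 0 over all genes, and Kcnq1ot1 and Neat1, which builds nuclear paraspeckles, were at 1.40 ± 0.42 and 0.98 ± 0.32. With the nuclear RNA level as a covariate the calls of the glycolysis (median -0.04, adjusted p = 0.581), actin (median 0.01, adjusted p = 0.923), microglia (median -0.06, adjusted p = 0.291) and nuclear-retained lists (median -0.04, adjusted p = 0.675) were lost. Late activity-response genes had a median of -0.08 (adjusted p = 0.0485; adjusted p = 0.772 with an estimated correlation), with Tiparp at -0.48 ± 0.14, Plk2 at -0.27 ± 0.09 and the activin subunit Inhba at 0.37 ± 0.10. That call was lost without iTBS 1 (adjusted p = 0.0687), iTBS 2 (adjusted p = 0.131), iTBS 4 (adjusted p = 0.0648), cTBS 4 (adjusted p = 0.182) or cTBS 5 (adjusted p = 0.123). It was lost too with the nuclear RNA level as a covariate, where the median was 0.10 (adjusted p = 0.172).

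Immediate early genes (median -0.10, adjusted p = 0.0533) and glucocorticoid-response genes (median -0.06, mean 0.04, adjusted p = 0.541) were not called between the protocols. The immediate early list was called lower without any of cTBS 1, cTBS 2, iTBS 3, iTBS 4, iTBS 5, sham 1, sham 2 or sham 5 (adjusted p from 0.00348 to 0.0473), and with the nuclear RNA and striatal levels as covariates (median -0.17, adjusted p = 0.00441). Fos was at -0.46 ± 0.20, Homer1 at 0.28 ± 0.11, Grin1 at 0.22 ± 0.10 and Gad1 at -0.21 ± 0.09. Among the genes with the smallest p, none of which passed (edgeR adjusted p = 0.0838), Osbpl3 was at 60.7 ± 9.16 CPM against 42.5 ± 3.02 (0.51 ± 0.09; 0.50 ± 0.07 and adjusted p = 0.0478 with a replicate block), Adgrl2, a latrophilin adhesion receptor, at 0.23 ± 0.04 and Krt20 at 0.75 ± 0.13. Txndc5, Ctsz and Ufc1 were at -0.34 ± 0.07, -0.31 ± 0.06 and -0.32 ± 0.07.

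**Figure D4:**
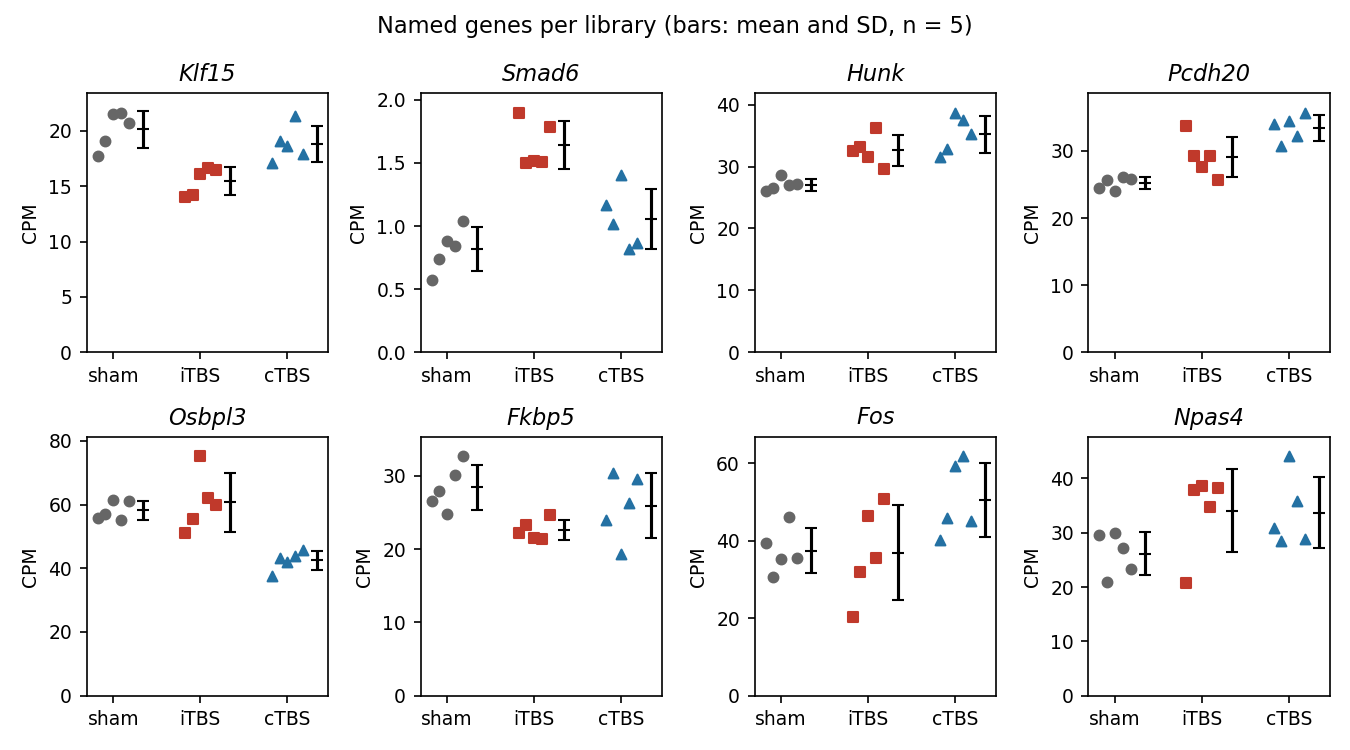
Levels of Klf15, Smad6, Hunk, Pcdh20, Osbpl3, Fkbp5, Fos and Npas4 in CPM on the y axis by group; each point is a library and the bars give the mean and SD (n = 5). Fos averages 36.9 CPM in iTBS, 50.4 in cTBS and 37.4 in sham, and none of the genes shown passed the edgeR threshold over all genes in the 3 comparisons with all 15 libraries and no block. With a replicate block Osbpl3 passed for iTBS against cTBS (edgeR adjusted p = 0.0478). Of 30 alternative fits, some with other tests or a library left out, Osbpl3 passed in 6 for iTBS against cTBS. For cTBS against sham, Pcdh20 passed in 4 of 30, Hunk and Osbpl3 in 3 each and Fos in 1.

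By edgeR, 0 of 22998 genes passed for iTBS against cTBS (smallest adjusted p = 0.0838), and 7047 had an unadjusted p under 0.05 (4600 higher, 2447 lower), against 1149.9 by chance. That number was 1780 with the nuclear RNA level as a covariate, 1789 with a surrogate variable, 3511 with the oligodendrocyte marker level and 4116 with the Y-linked gene level. DESeq2 called 2699 genes (1742 higher, 957 lower), limma-voom with quality weights 6853 (4508 higher, 2345 lower) and limma-trend 0; edgeR called 5 with a replicate block, 4474 without iTBS 1, 3380 without cTBS 5 and 3637 without sham 4. In nuclear RNA level iTBS 1 was the lowest of its group (7.04) and cTBS 5 the highest of its group (7.31). Groups without overlap were found in 3.92% of genes, against 0.794% by chance. Of 43 lists, 18 were called (1 higher, 17 lower) with the preset correlation and 0 with an estimated correlation. This split also moved with the nuclear RNA level as a covariate, where 18 were called as 9 higher and 9 lower, and with the striatal level added 17, as 9 higher and 8 lower.

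In a test for any difference among the 3 groups, edgeR called 0 genes (smallest adjusted p = 0.162), with 5316 at unadjusted p under 0.05, and 1259 with the nuclear RNA level as a covariate. DESeq2 called 938, limma-voom with quality weights 5269 and limma-trend 0, and edgeR called 3724 without sham 4. The responses to iTBS and cTBS, each against the same sham libraries, had a Pearson correlation of 0.0756 across 22998 genes, which are not independent replicates. Unchanged groups that share sham libraries gave 0.510 ± 0.00575 (SD, 20 simulations), and the covariance was 0.00260 against 0.0400 simulated. The simulations drew each gene independently. Their SDs, here and for the shared genes below, leave out the correlation between genes and do not measure the spread of the real values. With the sham libraries split between the comparisons the median correlation was -0.128 (-0.726 to 0.512 over 20 splits). Without sham 4 the correlation was 0.510, and without iTBS 1 it was -0.207. At unadjusted p under 0.05, 54 genes were higher after both protocols and 26 lower. Unchanged groups that share sham libraries gave 139 ± 9.85 higher and 101 ± 8.32 lower (SD, 20 simulations), and independent lists would give 14.9 and 39.5. With the sham libraries split between the comparisons the median was 7 genes higher (14.4 for independent lists) and 8 lower (30.5). Of 129 tests of list levels, 21 had an exact permutation p under 0.05 and 0 passed adjustment (smallest adjusted p = 0.271). At the smallest exact p of 0.00794, which 2 tests reached, none can pass unless at least 21 do together.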

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

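In 384 groups of 5 libraries, 19 held a library set apart from the rest, where its gap to the nearest library exceeded 0.71 of the group's range; chance gives about 1 in 20, or 19.2. The measures were library totals and compositions, the named genes and the described lists, the last 2 picked from the group comparisons. A single library can bring a list and its members into such a pick. The call of the thalamic markers for iTBS against sham was lost without sham 2 (camera, adjusted p = 0.528). Lists and their members also overlap, so the number by chance is only a guide. No test in this part was chosen after its result was seen. The libraries set apart fell most often on sham 2 (5), iTBS 1 (3) and cTBS 4 (3).

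Markers of thalamus stood apart in sham 2. Their mean level there was 5.39 (log2 CPM), with 3.81 in the nearest sham library. Prkcd was at 65.1 CPM in sham 2, Tcf7l2 at 47.6 CPM and Calb2 at 25.7 CPM. In the cTBS group, Prkcd was highest in cTBS 1 at 14.7 CPM and Calb2 in cTBS 2 at 15.02 CPM. Slc16a1, a lactate transporter gene, was also highest in sham 2 among sham libraries, at 32.9 CPM.

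Markers of meninges and choroid plexus stood apart in cTBS 4, where the meningeal and fibroblast level was 3.15 (log2 CPM), and the choroid plexus genes Kl and Sostdc1 were at 15.5 and 2.07 CPM. Col1a2, a collagen gene, was highest in iTBS 3 at 63.3 CPM. Rarb, a striatal marker, was highest in iTBS 2 at 15.4 CPM.

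In iTBS 1, Npas4 was lowest of the group at 20.7 CPM and Arrdc2 lowest at 4.26 CPM, while Psmb3, a proteasome gene, was highest at 35.3 CPM. In cTBS 5, Sdhb was lowest at 60.5 CPM and Cdc42 lowest at 213 CPM. Tmsb4x was highest in sham 4 at 289 CPM, and Inhba highest in sham 5 at 27.3 CPM.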

How the results depend on the processing

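Tests chosen only after the result was seen were the nuclear RNA covariate, alone and with the striatal level, the library number in list tests, the split of sham libraries for shared genes and the fit without sham 2, sham 5 and cTBS 4. Median-of-ratios scaling, the stricter filter, fits of a pair of groups alone, limma-trend and each covariate left the gene counts at 0 by edgeR or limma-trend. DESeq2 called 471 genes for cTBS against sham, 2699 for iTBS against cTBS and 938 among the 3 groups; limma-voom with quality weights called 5461, 6853 and 5269. Without an expression filter, 28 lists were called for cTBS against sham and 30 for iTBS against cTBS. With an estimated correlation 0, 0 and 0 lists were called for iTBS against sham, cTBS against sham and iTBS against cTBS, and with fry 0, 0 and 1. Splitting the sham libraries moved the correlation of the responses to -0.128, and the genes higher and lower after both protocols to medians of 7 and 8. The cause was not tested for any of these, except that a preset correlation of 0.01 lies below the median estimated correlation of 0.333 for cTBS against sham.

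Leaving out each library gave 0 to 5726 genes for cTBS against sham, 0 to 4474 for iTBS against cTBS, 0 to 3724 among the 3 groups and 0 to 0 for iTBS against sham. Called lists ran from 8 to 20, 15 to 21 and 16 to 23, and the correlation of the responses from -0.207 (without iTBS 1) to 0.510 (without sham 4). Where leaving out a library gave 3380 genes or more, that library was at an end of its group in nuclear RNA level. Sham 4 (6.50) and iTBS 1 (7.04) were lowest of their groups, and cTBS 5 (7.31) was highest. A wider gap in nuclear RNA between groups without them is a candidate explanation. It does not cover the 3637 genes for iTBS against cTBS without sham 4, a library outside that comparison. Without cTBS 5, 0 genes passed for cTBS against sham. The cause was not tested. Tests of list levels say nothing of stability: at their smallest exact p of 0.00794 none can pass unless at least 21 do together, and the sign-flip test over 5 replicate numbers cannot go below 0.0625.

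With the replicate number as a block, edgeR called 5 genes for iTBS against cTBS (Osbpl3 higher, Crym, Zcchc12, Htr2c and Lhfpl3 lower, all but Osbpl3 named after their values were seen), and 0 in the other comparisons and among the 3 groups. Replicate numbers did not pair the libraries: 7 of 15 pairs of the same number had a correlation of deviations over 0.1 (-0.564 to 0.717), and 5 of 15 libraries lay closest to their own number. The block gave 14, 19 and 22 lists, against 14, 18 and 18 without it, and a correlation of responses of -0.0552, against 0.0756.

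Lists called with the nuclear RNA level as a covariate numbered 10, 14 and 18 for iTBS against sham, cTBS against sham and iTBS against cTBS, with 4, 5 and 9 higher; with the striatal level added 12, 13 and 17, with 5, 4 and 9 higher. Directions of list tests turned in the following cases. With the nuclear RNA level as a covariate, medians for cTBS against sham were -0.0063 for actin genes, 0.0191 for nuclear-retained RNAs and -0.114 for late activity-response genes (adjusted p = 0.00114), and for iTBS against cTBS 0.0110, -0.0385 and 0.101. With the striatal level added, medians for cTBS against sham were -0.0045 for oligodendrocyte markers, -0.0184 for GABA genes, -0.0126 for actin genes and 0.0619 for nuclear-retained RNAs, and for iTBS against cTBS -0.0442 for nuclear-retained RNAs and 0.0021 for late activity-response genes. The covariate is itself the mean of the nuclear-retained list, which sets that list near 0 by construction. Without sham 2, sham 5 and cTBS 4 the choroid plexus median for iTBS against sham was 0.353 (adjusted p = 0.0366), by leaving out the libraries highest in it. The cause was not tested for the others. Apart from leaving out libraries, 350 values of described lists were recomputed, and 245 stayed on their side of the threshold, in the same direction where called. With the direction kept, 81 lost the call and 11 gained it. The other 13 are the turned directions above, most of which lost the call as well. Leaving out single libraries, 24 of 525 lost the call and 12 gained it. Named genes changed sign in 113 of 4289 recomputed values, over 26 pairs of gene and comparison, in no case past the threshold; the genes named for the smallest p changed sign in 0. Depth limits which genes were tested: thinned to 15385070 counts per library, 19557 genes passed the filter (mean of 10 thinnings) against 22998.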

Other observations

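Chosen only after the result was seen were the test of the nuclear RNA covariate on the number of genes, the test of genomic DNA on the rise of Malat1, the use of 10 thinnings in place of 1 and of 100 splits in place of 40 for DESeq2, and the condition that a value pass its bound by more than its spread. That condition changed 2 verdicts from against an explanation to open: nuclear RNA and time of day for the immediate early genes.

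Groups not described so far were called in the protocol contrast, iTBS against cTBS, with the preset correlation. Their calls were not followed one by one with the nuclear RNA level as a covariate or with a library left out. With that covariate the calls in this contrast went from 1 higher and 17 lower to 9 higher and 9 lower. Neuropeptide genes were lower after iTBS than after cTBS (median log2 fold change -0.19, 12 of 16 lower, camera adjusted p = 0.00473; adjusted p = 0.372 with an estimated correlation), with 2 passing adjusted over the list alone. Of its members Pdyn, Tac1 and Penk are also striatal markers, and markers of other regions moved the same way. Striatal projection neuron markers had a median of -0.51 with 18 of 18 lower (adjusted p = 6.89e-04; adjusted p = 0.690 with an estimated correlation), with an exact permutation p of 0.230 for their mean level, and hippocampal neuron markers a median of -0.32 with 12 of 13 lower (adjusted p = 0.0127; adjusted p = 0.448 with an estimated correlation). The mean level of the hippocampal markers was 1.99 ± 0.11 (log2 CPM, SD, n = 5) in iTBS and 2.30 ± 0.40 in cTBS. Of these markers C1ql2 and Fibcd1 were highest in cTBS 5, at 3.66 and 17.4 CPM. The nearest cTBS values were 1.73 and 11.1 CPM. Wfs1 was highest in cTBS 2, at 138 CPM. Layer 6 neuron markers had a median of -0.23 with 11 of 11 lower (adjusted p = 0.00254, and 0.372 with an estimated correlation), while layer 4 markers (0.08, adjusted p = 0.750) and upper-layer markers (-0.00, adjusted p = 0.318) were not called. The mean level of layer 5 markers was 4.53 ± 0.13 (log2 CPM, SD, n = 5) in iTBS and 4.67 ± 0.05 in cTBS (exact permutation p = 0.0794, adjusted p = 0.277). Differences between layers were not tested. Inhibitory interneuron markers had a median of -0.14 (adjusted p = 0.00722; adjusted p = 0.372 with an estimated correlation) and astrocyte markers -0.15 (adjusted p = 0.00192; adjusted p = 0.521 with an estimated correlation). The mean level of oligodendrocyte precursor markers was 4.10 ± 0.08 (log2 CPM, SD, n = 5) in iTBS and 4.28 ± 0.08 in cTBS, without overlap (exact permutation p = 0.00794, the smallest possible, adjusted p = 0.271). That of thalamic neuron markers was 3.67 ± 0.03 in iTBS and 3.90 ± 0.09 in cTBS, also without overlap and with the same p, while camera did not call that list (adjusted p = 0.202). Interferon-response genes, heat shock and unfolded protein genes, and AMPA and kainate receptor genes were not called in that contrast (adjusted p = 0.740, 0.640 and 0.937).

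Other assignments of the libraries to groups show how much chance gives. For iTBS against sham chance cannot be excluded: the 443 genes at unadjusted p under 0.05 were matched by 69 of 100 splits (highest other 8070) and the 14 lists by 76 (highest other 31). For cTBS against sham it cannot be excluded for the 5623 at unadjusted p (5 of 100, highest other 10305), the 18 lists (40 of 100, highest other 28) or the 5461 genes of limma-voom (8 of 100, highest other 9184). The 471 genes of DESeq2 were matched by 4 of 100 (highest other 10186), too near 5 in 100 to exclude chance. For iTBS against cTBS the 7047 genes at unadjusted p were matched by 3 of 100 splits (highest other 9230). Their number was 1780 with the nuclear RNA level as a covariate. The 2699 genes of DESeq2 were matched by 3 of 100 (highest other 7510), and by 3 of the first 40. Taken singly, both shares of 100 lie below 5 in 100. They were not adjusted over the split tests, so chance is not excluded. Nor is it for the 18 lists (44 of 100, highest other 30) or the 6853 genes of limma-voom (5 of 100, highest other 8268). For the counts of 0 genes past the adjusted threshold the splits say nothing of chance, since any split matches a count of 0 (100 of 100 each). The highest other counts were 2180 for iTBS against sham, 7982 for cTBS against sham, 6165 for iTBS against cTBS and 3734 among the 3 groups. Of 99 other splits, 3, 1, 1 and 1 called any gene in turn, and 1 of the 3 for iTBS against sham called 2 genes. What these few splits share was not tested.

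The excess of genes at unadjusted p under 0.05 for cTBS against sham (5623, 1149.9 by chance) was set against depth and nuclear RNA. With every library thinned to 15385070 counts, 4702 ± 157 genes had such a p (SD, 10 thinnings; 978 by chance; on average 3819 of them among the 5623), which is 24.0 ± 0.814% of the genes tested, against 24.45% unthinned. The mean lies 203 genes above the bound set against depth, 80% of the unthinned count, which is more than 1 SD and less than 2, with 9 of the 10 thinnings above it (4410 to 4886 genes). This argues against unequal counting precision from depth as the cause of the excess in this comparison. Thinning cannot remove a property of the libraries that goes with depth, and the nuclear RNA level follows log2 total counts (r = -0.655 over deviations from group means). Thinning was not run for iTBS against cTBS. With the nuclear RNA level as a covariate 1338 genes had such a p, 590 of them among the 5623, and the median size of the log2 fold changes of the 5623 genes went from 0.85 to 0.16 with the median SE from 0.33 to 0.22, so a candidate explanation is an unequal share of nuclear RNA. The level is lower in cTBS than in sham by 0.81 (log2), so whether stimulation or tissue handling set it was not tested.

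The libraries with much nuclear-retained RNA may hold more unspliced or nuclear RNA, or genomic DNA. Sense-intronic and unclassified genes rose with the nuclear RNA level by a median slope of 1.253 (log2 per log2, 1994 genes), against -0.06 for 15247 protein-coding genes, which fits more unspliced or nuclear RNA. Genomic DNA would add reads to such genes too, so this slope does not tell these explanations apart. The share of counts in 1736 olfactory and vomeronasal receptor genes, which cortex barely transcribes, rose with a slope of 0.899 ± 0.0682 (SE), between that of Malat1 (1.46) and the bound against genomic DNA, so DNA cannot be told apart from low nuclear transcription. DNA does not account for Malat1 itself: from cTBS 4 to sham 3 the mean CPM per receptor gene rose by 0.000584% of the rise in Malat1.

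The level of immediate early genes rose with the library number over deviations from group means in 15 libraries (Pearson r = 0.742, permutation p = 0.00143, adjusted p = 0.00334 over 7 relations; Spearman rho = 0.693, permutation p = 0.00566; r = 0.751 without the 2 farthest libraries). It also followed the level of glucocorticoid-response genes that the lists do not share (r = 0.792, permutation p = 0.00052, adjusted p = 0.00182, rho = 0.739, permutation p = 0.00238, and r = 0.778 without the 2 farthest). Unequal stress hormone exposure is a candidate explanation. The full glucocorticoid-response level rose with the library number too (r = 0.810), and that number was not taken out of this relation. The immediate early level therefore cannot tell hormone exposure apart from another factor that goes with the library number. Its relation to the nuclear RNA level was r = -0.146 (permutation p = 0.603, adjusted p = 0.603; rho = -0.186, permutation p = 0.508; 0.252 without the 2 farthest), and that of a clock-phase index to the library number was r = -0.285 (permutation p = 0.3003, adjusted p = 0.420; rho = -0.214, permutation p = 0.439; -0.316 without the 2 farthest). Their approximate 95% intervals, -0.645 to 0.440 and -0.723 to 0.316, include the size of 0.5 that either explanation needs, so both stay open. What the library number stands for is not given in the sources used here.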
